A study of Mus musculus with 8 samples.

How the data were processed

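RNA was sequenced from 8 samples of mouse bone marrow cells carrying MLL-AF10, 2 each of MAflox cells with ethanol, MAflox cells with 4-OHT, MATIP cells with ethanol and MATIP cells with 4-OHT. Per the labels' protocols the cells grew in methylcellulose with SCF, IL-3 and GM-CSF, were treated with 100 nM 4-OHT or ethanol for 4 days, and total RNA was taken with a Qiagen RNeasy Plus kit and made into libraries by standard Illumina protocols. Groups and replicate numbers were taken from the sample titles.

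The deposited count table holds whole-number read counts per gene symbol, one column per library, not normalized. Per the submitters' processing notes the tools were Trimmomatic 0.38.0, HISAT2 2.1.0, featureCounts 1.6.4 and DESeq2, and the build was mm10. Strandedness, the handling of reads that map to several places and the gene annotation are not given in the sources used here. The count file also has 23 empty columns and 0 filled columns without a sample. A second table holds, per the file headers, the authors' log2 fold changes between 4-OHT and ethanol in each line. Per the file headers it also holds the authors' adjusted p-values of those comparisons, which are empty for many genes and are 0 for 75. The direction of the authors' log2 values was checked against the counts.

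Library totals were 41101309 to 57312490 counts. Of 24421 gene symbols 17831 had at least 1 count. Genes passing edgeR's filterByExpr by group (minimum count 10, minimum total 15) numbered 13722 and were tested. Counts were scaled with TMM factors, and the main test was the edgeR 4.0.16 quasi-likelihood test (R 4.3.3) on all 8 libraries with 1 coefficient per group and no covariate, so that the 4 groups shared 1 estimate of the spread (4 residual degrees of freedom, prior degrees of freedom 14.3, common biological coefficient of variation 5.98%). Contrasts were 4-OHT against ethanol in each line, the difference of these 2 responses, and MATIP against MAflox in ethanol. P-values were adjusted by Benjamini-Hochberg within a contrast and called at 0.05. The standard error of a log2 fold change is its size over the square root of the test's F statistic. Replicates of a group differed by more than sampling noise (chi-square over degrees of freedom 7.09 to 13.1), so no pair was treated as 1 library. A fold against a group with 0 counts was set against a floor of 3 counts over the group, and with 1 to 3 counts a ratio is given with a 95% counting interval.

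Before the data were examined, 21 gene lists, the contrasts, the alternatives and the rule for named genes were fixed. The lists cover MLL fusion targets, progenitor genes, monocytes and macrophages, primary granules, mature neutrophils, mast cells and basophils, eosinophils, dendritic cells, erythroid cells and megakaryocytes, lymphoid cells, stromal cells, S phase, mitosis, p53 targets, ribosome biogenesis and MYC, the TIP60 complex, MLL and AF10 cofactors, sterol synthesis, interferon response, integrated stress, and immediate-early and heat shock genes. Of 494 list members 489 were in the count table, 3 of them under an older symbol (such as H2afv), and Ly6g, Ighm, Igkc, Trbc1 and Trbc2 were not matched. Some genes stand in more than 1 list, such as Myb, Flt3 and Nkg7. The list of MLL and AF10 cofactors holds Kmt2a and Mllt10 themselves, and the TIP60 complex list holds Kat5, the gene floxed in MATIP cells. Fractions of a list are of its members that passed the count filter, such as 5 of 24 in the lymphoid list. Lists were tested with camera from limma 3.58.1 with a preset correlation of 0.01, adjusted over the 21 lists of a contrast, and again with the correlation estimated. Fry from limma, which tests a list's own genes without setting them against other genes, was run beside it. A further 5 lists (lysosome, oxidative phosphorylation, phagocyte NADPH oxidase, chemokines, ribosomal proteins) were written after the data were seen.

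Named genes were, for each treatment contrast, Kat5, Kmt2a, Mllt10, Hoxa9 and Meis1, the 8 largest rises and 8 largest falls among called genes whose treated libraries both lay above or both below the controls and whose mean was at least 5 CPM over those libraries, without predicted genes, and the 2 called members of each list with the smallest p (or, with none called, the member with the smallest p). For the difference of responses the same 5 genes and 6 per direction were named, and for the ethanol baseline 5 per direction. Of the genes named by this rule, 3 are not reported here. Gene positions, GC content and transcript lengths come from GENCODE M21, whose assembly is mm10. Of the symbols 23334 were found there once, and GC content and length were known for 96.4% of tested genes.

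Tests were run first on simulated counts for the 13722 genes, drawn from the real means and library sizes, with 200 genes changed in treated MATIP libraries. For the MATIP contrast, run on 13352 genes after filtering, edgeR recovered 42 of 63 genes changed by 0.5 on the log2 scale, 56 of 66 changed by 1 and 58 of 65 changed by 2. It called 165 genes there, 9 of them unchanged. For the difference of responses, also on 13352 genes, it recovered 30 of 63, 52 of 66 and 54 of 65. It called 147 genes there, 11 of them unchanged, and DESeq2 called 154, 16 of them unchanged. In the MAflox and baseline contrasts, where nothing was changed, edgeR called 0 of 13352 genes, DESeq2 called 0 of 13722 and limma-voom 0 of 13352. With the replicate block edgeR called 1 of 13352 genes in the MAflox contrast. Camera found the planted list of 30 genes in the simulated MATIP contrast and passed 0 of 20 unchanged lists. Genes were drawn independently there, while estimated correlations within real lists reached values such as 0.78 (ribosomal proteins, MAflox contrast). The simulation therefore does not test camera's preset correlation on lists of correlated genes. Its 200 changes were as many up as down and at most 2 on the log2 scale. The real contrasts called 65.2% of genes in MAflox and 76.1% in MATIP cells. It therefore does not test the scaling under changes this broad, and its recovery and false calls need not hold for the real contrasts.

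Alternatives chosen before the data were seen were median-ratio and upper-quartile factors, no count filter, a filter at a mean of 5 CPM, DESeq2 1.42.0, limma-voom, a fit to only the libraries compared, the replicate number within a line as a block, and leaving out each of the 8 libraries in turn. Alternatives added after the data were seen were a test for changes above 1.5-fold (glmTreat), scaling without the 200 most abundant genes, median-ratio and upper-quartile factors for the lists, and the removal of a loess trend (span 0.5) of the fold change on GC content and log2 transcript length, fitted robustly or by ordinary least squares. Intervals of list medians are 95% intervals from order statistics. They treat the members of a list as independent, which they are not, and hold no spread between libraries. Where members move together these intervals are too narrow. Groups of 2 libraries are too small for tests of single outlying libraries or of other splits of the samples.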

Results

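Gene counts were measured by RNA sequencing in mouse bone marrow cells carrying MLL-AF10, a leukaemia fusion of the histone methyltransferase MLL (gene Kmt2a) with AF10 (gene Mllt10). Cells of 2 lines were compared, both from the strain C57BL/6 and grown in methylcellulose with SCF, IL-3 and GM-CSF. MAflox cells are called MLL-AF10 flox cells in the labels, and the labels do not say whether they carry Cre-ERT2. MATIP cells carry MLL-AF10, floxed alleles of Tip60 (the histone acetyltransferase encoded by Kat5) and Cre-ERT2, a recombinase activated by 4-hydroxytamoxifen (4-OHT). Each line was treated for 4 days with 100 nM 4-OHT or with ethanol (EtOH), with 2 libraries in each of the 4 groups. The 8 libraries held 41101309 to 57312490 gene counts and 14380 to 15822 detected genes. The 20 most abundant genes took 7.27% of counts in MAflox EtOH, 11.5% in MAflox 4-OHT, 7.38% in MATIP EtOH and 17.3% in MATIP 4-OHT (means, n = 2 each). The first 2 principal components of the log2 values held 64.5% and 22.0% of the variance. The labels do not say that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Levels are counts scaled to library size as CPM (mean ± SD, n = 2 libraries), and log2 fold changes are given ± the standard error (SE) of the fit to 8 libraries. A gene is said to rise, fall or change where its edgeR quasi-likelihood p, adjusted by Benjamini-Hochberg over 13722 genes, passed 0.05.

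Kat5, the gene floxed in MATIP cells, fell there from 41.2 ± 0.100 to 8.22 ± 0.154 CPM with 4-OHT, a log2 change of −2.32 ± 0.09 (5.01-fold; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 6.99e-15). In MAflox cells Kat5 rose from 42.4 ± 1.78 to 60.0 ± 3.55 CPM, a log2 change of 0.50 ± 0.07, and the difference between the responses was −2.82 ± 0.11. Kmt2a, which encodes the amino-terminal part of the fusion, fell in MAflox cells from 41.3 ± 11.2 to 18.8 ± 3.69 CPM (log2 −1.13 ± 0.16). In MATIP cells Kmt2a went from 41 ± 3.04 to 54.1 ± 10.3 CPM, log2 0.40 ± 0.15, with an adjusted p of 0.0207 (edgeR quasi-likelihood, Benjamini-Hochberg). That call was lost with DESeq2 (adjusted p = 0.132) and in edgeR without MATIP EtOH replicate 1 (adjusted p = 0.0792) or without MATIP 4-OHT replicate 1 (log2 0.23, adjusted p = 0.252). In the authors' deposited table this gene passed in MATIP cells (DESeq2 adjusted p = 0.000798). Kmt2a responses differed by 1.53 ± 0.21. With a trend of the fold change on transcript length and GC content removed, its log2 changes were −0.59 in MAflox and 0.07 in MATIP cells and its difference 0.79. Mllt10, which encodes the carboxy-terminal part, fell by 0.35 ± 0.06 on the log2 scale in MAflox and by 0.90 ± 0.06 in MATIP cells. Counts per gene do not separate endogenous transcripts from those of the fusion, and the labels do not say which exons are floxed.

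On the mm10 assembly, Kat5 lies on chromosome 19 at 5603014 to 5610237, Kmt2a on chromosome 9 at 44803355 to 44881296, Mllt10 on chromosome 2 at 18055237 to 18212388, Hoxa9 on chromosome 6 at 52223100 to 52231089 and Meis1 on chromosome 11 at 18879817 to 19018985. All 5 are annotated as protein-coding. Of the 114 genes named by the rule, 40 share exon bases with another annotated gene, 29 of them with a gene on the opposite strand. Kat5 shares 426 bases with Rnaseh2c and Mllt10 shares 749 with Dnajc1. Since no source used here gives the strandedness of the counting, counts over shared bases are uncertain for these genes.

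**Figure D1:**
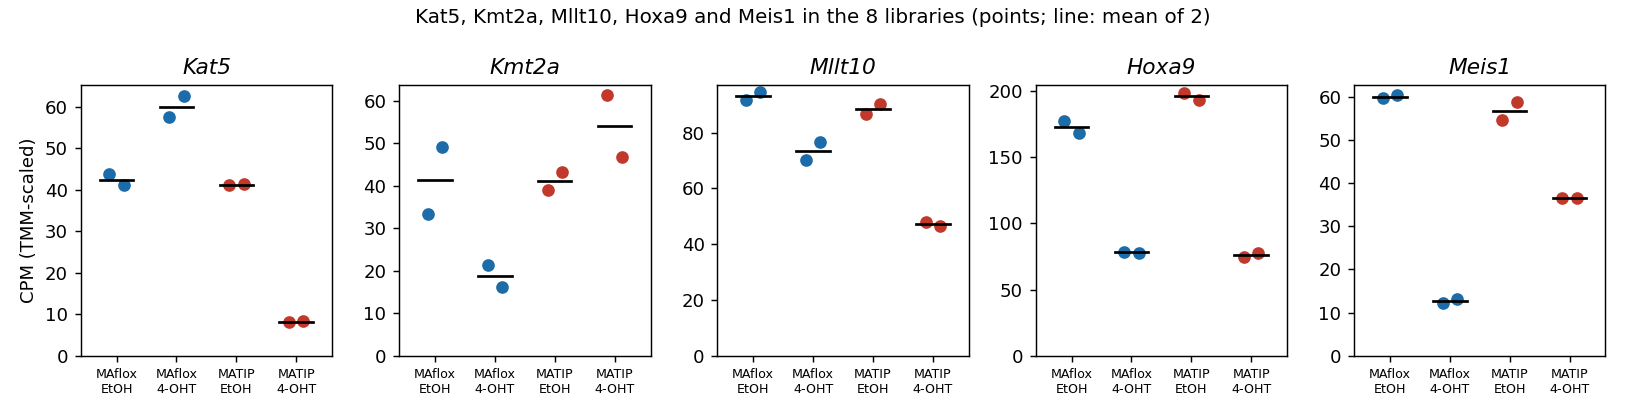
CPM (TMM-scaled, linear axis from 0) of Kat5, Kmt2a, Mllt10, Hoxa9 and Meis1 in each of the 8 libraries (points), with the mean of the 2 libraries of each group as a line. Kat5 averaged 8.22 CPM in the treated MATIP libraries against 41.2 in their controls, and Meis1 averaged 12.7 CPM in treated MAflox libraries against 60.0.

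The first comparison asked how 4-OHT changed the transcriptome of MAflox cells. Genes of mature neutrophils rose most. All 23 tested members of the mature neutrophil list rose, with a median log2 change of 6.47. Camp, the antimicrobial peptide cathelicidin of secondary granules, went from 4.22 ± 0.107 to 1747 ± 38.5 CPM (log2 8.70 ± 0.10), and S100a8, a subunit of calprotectin, from 67.5 ± 4.09 to 14542 ± 475 CPM (log2 7.75 ± 0.09). Among the 8 largest rises were Ltf, which encodes lactoferrin (log2 9.79 ± 0.12), the stefin A protease inhibitors Stfa3 (10.12 ± 0.17) and Stfa2 (8.82 ± 0.09), Ceacam10 (9.06 ± 0.19) and Ifitm6 (8.90 ± 0.11). The chemokine gene Cxcl3 had 0 counts in both EtOH libraries and was at least 514-fold higher with 4-OHT, against a floor of 3 counts over the group. Ankrd22 and Retnlg had 2 counts each over the EtOH libraries, and their ratios had 95% counting intervals of 527 to 15741 and 206 to 6160. Intervals and floors cover counting error only.

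Macrophage genes rose as well. Of 27 monocyte and macrophage genes 21 rose and 3 fell (median log2 1.85, or 2.01 without a member at 0 counts in both groups). Those with the smallest p were Lyz2, lysozyme M (log2 4.97 ± 0.07, to 4225 ± 138 CPM), and Spp1, osteopontin (3.64 ± 0.08). Primary granule genes parted: 9 of 12 rose, among them Elane, neutrophil elastase (1.20 ± 0.06), and 3 fell, among them Mpo, myeloperoxidase (−1.44 ± 0.05), with a median of 0.54 that was 0.31 (95% interval −0.50 to 0.91) with the trend on transcript length and GC content removed. By camera, which compares a list with all other genes, the mature neutrophil list had an adjusted p of 7.23e-111 (adjusted p = 0.0120 with an estimated correlation) and the monocyte and macrophage list 1.91e-18 (adjusted p = 0.0222 with an estimated correlation). The primary granule list did not pass (camera adjusted p = 0.0658).

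Targets of MLL fusions fell. Of 29 tested targets 26 fell and 2 rose (median log2 −1.49; camera adjusted p = 2.27e-13, adjusted p = 0.0120 with an estimated correlation). Hoxa9 and Meis1, homeobox genes that MLL fusions keep active, fell by 1.14 ± 0.06 and by 2.24 ± 0.08 on the log2 scale, and the transcription factor gene Mef2c had a log2 change of −2.89 ± 0.06. Flt3, a receptor tyrosine kinase of progenitors (−3.50 ± 0.26), and Mecom, the EVI1 transcription factor (−3.32 ± 0.20), were among the 8 largest falls with C2cd4a (−4.26 ± 0.35), Adgrl4 (−4.00 ± 0.24), Armcx4 (−3.33 ± 0.15), Bhlha15 (−3.21 ± 0.18), Col19a1 (−3.17 ± 0.19) and Cgnl1 (−3.13 ± 0.09). Of 20 progenitor genes 12 fell, Cd34 among them (−2.30 ± 0.09), and 2 rose, including Prom1 (3.15 ± 0.08; camera adjusted p = 0.0175, adjusted p = 0.175 with an estimated correlation). In the list of MLL and AF10 cofactors 14 of 16 fell (camera adjusted p = 0.000774, adjusted p = 0.179 with an estimated correlation). Kmt2a and Mllt10 themselves are in that list and among the falls. Dot1l, a histone methyltransferase that AF10 binds, was at −1.39 ± 0.07 and Kmt2b at −1.34 ± 0.07. Subunits of the TIP60 complex went both ways, with 5 of 20 higher (H2afv, 1.22 ± 0.07) and 11 lower (Ep400, −1.44 ± 0.08), and the list did not pass (camera adjusted p = 0.153).

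Growth genes fell. All 35 genes of ribosome biogenesis and MYC targets fell (median log2 −0.86; camera adjusted p = 2.68e-16, adjusted p = 0.179 with an estimated correlation), including Cad, the first enzyme of pyrimidine synthesis (−2.54 ± 0.07), and Utp20 (−2.29 ± 0.08). Replication genes of S phase fell in 19 of 30 and rose in 5, with Dnmt1 at −1.05 ± 0.06 and Pole at −1.40 ± 0.08 (camera adjusted p = 0.00396, adjusted p = 0.199 with an estimated correlation). Mitotic genes went both ways, 8 of 30 up and 11 down, with Cenpe at −1.19 ± 0.06 and Plk1 at −0.89 ± 0.06, and the list did not pass (camera adjusted p = 0.222). Among p53 targets 21 of 33 rose and 7 fell (camera adjusted p = 0.00483, adjusted p = 0.117 with an estimated correlation), with Trp53inp1 at 3.14 ± 0.09 and Btg2 at 2.68 ± 0.10. Interferon response genes rose in 20 of 27, including Zbp1 (3.30 ± 0.19; camera adjusted p = 0.0121, adjusted p = 0.486 with an estimated correlation).

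Markers of other cell types were also scored. In the eosinophil list 8 of 10 genes rose (median log2 3.04; camera adjusted p = 0.0118, adjusted p = 0.175 with an estimated correlation), including Siglecf (2.86 ± 0.17) and Ear2 (4.70 ± 0.33). The mast and basophil, dendritic, erythroid and megakaryocyte, lymphoid and stromal lists did not pass, with camera adjusted p of 0.247, 0.848, 0.319, 0.520 and 0.446. Of the tested members 10 of 13, 7 of 14, 6 of 10, 2 of 5 and 6 of 10 rose. The fixed lists held 22, 18, 20, 24 and 15 genes, so these are not shares of the whole lists. The count filter also passes a gene counted in only 1 group, which favours members that differ between groups. Of these lists 3 dendritic members and 1 stromal member fell. With members at 0 counts in EtOH set to their bound, the mast and basophil median was 1.65 in place of 2.18 and the stromal median 0.95 in place of 1.20. The members with the smallest p were Mitf (0.92 ± 0.12) and Hdc (0.75 ± 0.10), Cd74, the invariant chain (1.94 ± 0.10), and Tcf4 (−1.92 ± 0.07), Pf4 (3.07 ± 0.35), Nkg7 (1.04 ± 0.07) and Cd79b (0.66 ± 0.14), and Acta2 (1.74 ± 0.17). Ppbp was at least 31.6-fold higher, with 0 counts in EtOH, and Col1a1, with 3 counts there, had a ratio of 16.4 to 241. Sterol synthesis, integrated stress and immediate-early genes did not pass either (camera adjusted p = 0.591, 0.453 and 0.0558), although single members changed, such as Fdps (1.34 ± 0.06), Shmt2 (−1.23 ± 0.06), Slc7a5 (−1.31 ± 0.06), Klf6 (2.34 ± 0.07) and Hsph1 (−1.57 ± 0.06).

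In all, 8947 of 13722 genes changed in MAflox cells, 4548 up and 4399 down, of which 1886 and 1138 moved at least 2-fold. The count of changed members was 29 adjusted over the list alone against 28 over all genes for MLL targets, 9 against 8 for eosinophil genes and 17 against 16 for the TIP60 complex, and equal for the other 18 lists. The fold changes followed transcript length in MAflox cells: the median log2 change was 0.31 in the shortest of 5 equal groups of genes (56 to 1848 bases) and −0.37 in the longest (5125 to 123179 bases), against −0.03 and 0.09 in MATIP cells. With this trend and that of GC content removed, Kmt2a, with a transcript of 16470 bases, went from −1.13 to −0.59 in MAflox cells and Mllt10 from −0.35 to −0.19. The median of the MLL and AF10 cofactors went from −0.63 to −0.39, that of ribosome biogenesis from −0.86 to −0.85 and that of mature neutrophil genes from 6.47 to 6.21.

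**Figure D2:**
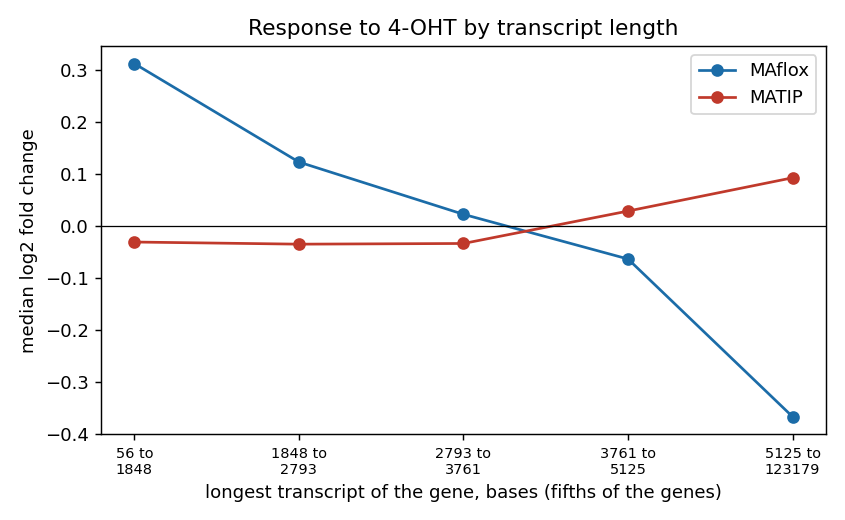
Median log2 fold change with 4-OHT (vertical axis) in 5 equal groups of the tested genes by the length of their longest transcript in bases (horizontal axis), in MAflox and MATIP cells. The MAflox medians run from 0.31 in the shortest to −0.37 in the longest group, and those of MATIP cells lie between −0.03 and 0.09.

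The second comparison asked the same of MATIP cells, which carry floxed Kat5 and Cre-ERT2. Macrophage genes rose in 25 of 27 members and fell in 1 (median log2 3.96). Spp1 went from 96.7 ± 1.40 to 8296 ± 302 CPM (log2 6.42 ± 0.09) and Lyz2 from 204 ± 14.2 to 8628 ± 436 CPM (5.40 ± 0.07). Mature neutrophil genes rose in 22 of 23 (median log2 5.59), with the collagenase gene Mmp8 at 6.09 ± 0.07 and Stfa2l1 at 7.43 ± 0.09. Primary granule genes fell in 9 of 12 and rose in 3, with Mpo going from 7908 ± 59.5 to 1641 ± 66.7 CPM (−2.27 ± 0.05) and Ctsg, cathepsin G, at −1.58 ± 0.05. Camera gave adjusted p of 6.4e-32 for macrophage genes (adjusted p = 0.0379 with an estimated correlation) and 1.93e-56 for mature neutrophil genes (adjusted p = 0.0208 with an estimated correlation). For primary granule genes it gave 6.13e-05 (adjusted p = 0.156 with an estimated correlation).

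Among the 8 largest rises were Klk1b11, a kallikrein (log2 10.01 ± 0.13), Prl2c5, of the prolactin family (9.94 ± 0.23), the potassium channel gene Kcnn3 (9.33 ± 0.25), Gprc5b (8.94 ± 0.36), Lyz1 (8.93 ± 0.28), Retnlg (8.77 ± 0.24) and Cxcl3 (8.67 ± 0.15). Klk1b11 stood at 207 ± 0.616 CPM with 4-OHT against 0.193 ± 0.0581 with EtOH. Over the MATIP EtOH libraries Kcnn3, Gprc5b, Lyz1 and Retnlg had 8, 4, 6 and 8 counts, so their sizes and ranks are uncertain. Klk1b, Prl2c, Stfa and Ear genes, and Lyz1 with Lyz2, have near-identical copies in the genome, and how the counting split shared reads is not given, so values of single members are uncertain. The 8 largest falls were Bcat1, the cytosolic branched-chain aminotransferase (−5.12 ± 0.10), Bhlha15 (−4.50 ± 0.23), Rpph1, the RNA of RNase P (−3.84 ± 0.37), the small nucleolar RNA host gene Snhg4 (−3.77 ± 0.17), Ccdc116 (−3.63 ± 0.19), choline dehydrogenase Chdh (−3.63 ± 0.08), Cldn11 (−3.44 ± 0.22) and the mucin gene Muc13 (−3.44 ± 0.07). Rpph1 shares 233 bases with Ccnb1ip1 on its own strand.

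Genes of cell division and growth fell. In the S phase list 28 of 30 fell (median log2 −1.19; camera adjusted p = 2.4e-11, adjusted p = 0.0512 with an estimated correlation), with the replicative helicase gene Mcm2 at −1.86 ± 0.05 and Uhrf1 at −1.62 ± 0.05. Mitotic genes fell in 29 of 30 (median log2 −1.27; camera adjusted p = 1.35e-14, adjusted p = 0.0745 with an estimated correlation), with Ube2c at −2.40 ± 0.07 and Cdc20, an activator of the anaphase-promoting complex, at −2.21 ± 0.06. Ribosome biogenesis and MYC targets fell in 34 of 35 (median log2 −1.79; camera adjusted p = 7.49e-25, adjusted p = 0.100 with an estimated correlation), with Pa2g4 at −2.54 ± 0.06 and Cad at −2.67 ± 0.07. TIP60 complex genes fell in 14 of 20 and rose in 5, with the AAA ATPase gene Ruvbl2 at −2.51 ± 0.06 (camera adjusted p = 0.00262, adjusted p = 0.270 with an estimated correlation). The floxed gene Kat5 is in that list and among the falls. In the p53 list 22 of 33 rose and 9 fell, with Trp53inp1 at 3.77 ± 0.09 and Plk2 at 5.29 ± 0.13 (camera adjusted p = 0.00269, adjusted p = 0.0745 with an estimated correlation).

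MLL fusion targets fell in 19 of 29 and rose in 6 (median log2 −1.18; camera adjusted p = 0.00977, adjusted p = 0.100 with an estimated correlation). Hoxa9 fell by 1.37 ± 0.06, Meis1 by 0.63 ± 0.07 on the log2 scale, Mef2c had −1.63 ± 0.06 and the progenitor transcription factor gene Myb −2.24 ± 0.05. Mecom had 0 counts in both MATIP groups. Progenitor genes went both ways, 7 up, with Cd93 at 1.69 ± 0.06, and 7 down of 20, and did not pass (camera adjusted p = 0.230), and neither did the cofactors (0.230), of which 5 of 16 rose and 8 fell, Men1, menin (−1.15 ± 0.07), and Psip1 (−1.01 ± 0.06) among them.

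Interferon response genes rose in 23 of 27 (median log2 3.66; camera adjusted p = 0.00180, adjusted p = 0.180 with an estimated correlation), including Irf7 (4.17 ± 0.24), while Gbp3 fell (−2.25 ± 0.11). Immediate-early and heat shock genes rose in 13 of 19 and fell in 5 (camera adjusted p = 0.000789, adjusted p = 0.0745 with an estimated correlation), with Klf6 at 4.16 ± 0.07 and the chaperone gene Hsph1 at −1.99 ± 0.06. Integrated stress genes fell in 18 of 24 and rose in 5, the falls including Phgdh of serine synthesis (−2.28 ± 0.06), while Slc7a11, the cystine transporter, rose (4.21 ± 0.08; camera adjusted p = 0.0390, adjusted p = 0.533 with an estimated correlation). Without MATIP 4-OHT replicate 1 this list's camera adjusted p was 0.0644. Sterol synthesis went both ways, with Hmgcs1 at 1.56 ± 0.06 (camera adjusted p = 0.525).

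Stromal markers rose in 9 of 10, with Fn1, fibronectin, at 4.47 ± 0.11 and Acta2 at 2.1 ± 0.15 (camera adjusted p = 0.00839, adjusted p = 0.100 with an estimated correlation). The fixed stromal, erythroid and megakaryocyte, and eosinophil lists held 15, 20 and 11 genes. Since the count filter favours members that differ between groups, the shares and p-values given for these lists are not those of the whole lists. Erythroid and megakaryocyte markers rose in 6 of 10, with Vwf at 6.21 ± 0.15 and Ppbp at 8.13 ± 0.35 (camera adjusted p = 0.0403, adjusted p = 0.156 with an estimated correlation). Eosinophil markers rose in 7 of 10 (median log2 5.12, or 2.34 with members at 0 counts set to their bound; camera adjusted p = 0.0454, adjusted p = 0.302 with an estimated correlation), with Ear2 at 6.55 ± 0.27 and Ear1 at 7.95 ± 0.38. Over the MATIP EtOH libraries Ppbp had 6 counts and Ear1 had 4, so the sizes of their changes are uncertain. The erythroid and eosinophil calls were also lost without MATIP 4-OHT replicate 1 (camera adjusted p = 0.0644 and 0.0719) or replicate 2 (0.0621 for each), with median-ratio factors (0.0581 for each) and with upper-quartile factors (0.0744 and 0.0772). Mast and basophil, dendritic and lymphoid markers did not pass (camera adjusted p = 0.510, 0.0754 and 0.334). Their members that rose were 7 of 13 (Mitf, 1.79 ± 0.11, and Hdc, 0.95 ± 0.10), 9 of 14 (Cd74, 4.03 ± 0.10, and Itgax, 5.19 ± 0.13) and 2 of 5, while 3, 4 and 3 fell, the last with Nkg7 (−1.74 ± 0.09) and Lck (−2.66 ± 0.26).

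MATIP cells changed in 10441 genes, 5144 up and 5297 down, of which 3103 and 1937 moved at least 2-fold. The counts of changed members adjusted over the list alone were 20 against 19 over all genes for the TIP60 complex and 14 against 13 for the cofactors, and equal for the other 19 lists. With median-ratio factors 5519 rose and 4932 fell, and with upper-quartile factors 5887 and 4551, and the direction with more genes turned in 10 of the 17 alternatives run, 4 of them leaving out 1 library. Upper-quartile scaling moved the median of all genes in MATIP cells from 0.00 to 0.15 on the log2 scale. Scaling without the 200 most abundant genes left it at 0.001.

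**Figure D3:**
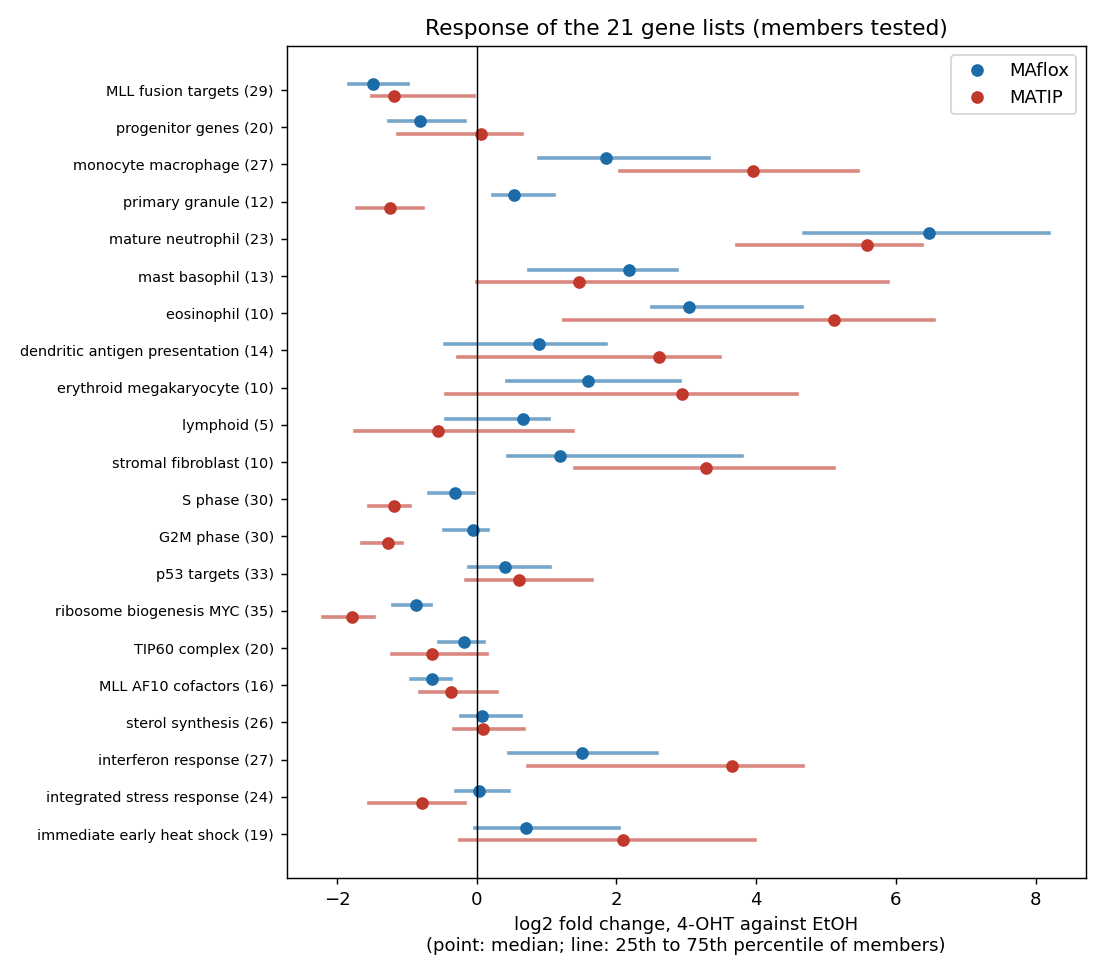
Median log2 fold change with 4-OHT (points) and the 25th to 75th percentile of members (lines) of the 21 gene lists in MAflox and MATIP cells, with the number of members tested in parentheses. The mature neutrophil medians are 6.47 and 5.59, and those of primary granule genes 0.54 and −1.24.

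The third comparison tested the difference between the responses of the 2 lines, as the interaction of line and treatment, given as MATIP minus MAflox. Primary granule genes had a lower response in MATIP cells in all 12 members (median −1.42, or −0.91 with the length and GC trend removed). Macrophage genes had a higher response in 22 of 27 and a lower one in 2 (median 2.07). Mature neutrophil genes had a lower response in 14 of 23 and a higher one in 5 (median −1.59), with Camp at −5.56 ± 0.12. Cell division genes had a lower response in 26 of 30 in S phase (median −0.88) and 28 of 30 in mitosis (median −1.21). MLL targets had a higher response in 14 of 29 and a lower one in 4 (median 0.53).

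The 6 most positive differences were Prl2c5 (7.61 ± 1.18), Klk1b11 (7.32 ± 0.58), the orphan nuclear receptor gene Nr4a3 (7.02 ± 0.95), Fam181b (6.43 ± 0.92), Gprc5b (6.40 ± 0.66) and the latrophilin gene Adgrl2 (6.23 ± 0.19). The 6 most negative were Camp, Fcnb, ficolin B (−5.30 ± 0.25), Smim6 (−5.25 ± 0.48), Fbxo17 (−5.22 ± 0.29), Ceacam10 (−4.97 ± 0.34) and Ankrd22 (−4.70 ± 0.72). The Ankrd22 value rests on 2 counts over the MAflox EtOH libraries, so its size and rank are uncertain. So are those of Gprc5b, with 4 counts over the MATIP EtOH libraries, and of Prl2c5, with 10 over the MAflox and 16 over the MATIP EtOH libraries. Meis1 fell more in MAflox cells (difference 1.61 ± 0.11), and Mllt10 more in MATIP cells (−0.56 ± 0.09). Hoxa9 differed by −0.23 ± 0.08 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0210), which did not hold with median-ratio factors (adjusted p = 0.111), upper-quartile factors (0.340), a stricter filter (0.240) or DESeq2 (0.134). Nor did it hold in edgeR without MAflox EtOH replicate 2 (0.0979), MAflox 4-OHT replicate 1 (0.0836) or 2 (0.0512), MATIP EtOH replicate 1 (0.0556) or MATIP 4-OHT replicate 1 (0.135).

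Camera passed 9 of the 21 lists for this difference, and none of the 9 with an estimated correlation. The camera adjusted p was 1.14e-12 for primary granule, 6.98e-12 for macrophage, 3.69e-08 for S phase, 1.46e-17 for mitotic genes and 0.00126 for MLL targets (adjusted p = 0.0761 with an estimated correlation for each of these 5). It was 3.59e-05 for mature neutrophil genes (adjusted p = 0.325 with an estimated correlation) and 2.18e-08 for ribosome biogenesis (adjusted p = 0.364 with an estimated correlation), where 25 of 35 had a lower and 2 a higher response. TIP60 complex genes had a camera adjusted p of 0.0254 (adjusted p = 0.384 with an estimated correlation), with 11 of 20 lower, Kat5 among them, and 5 higher. Immediate-early genes had 0.0263 (adjusted p = 0.179 with an estimated correlation), with 11 of 19 higher and 5 lower. Without MATIP 4-OHT replicate 1 or 2 the camera adjusted p was 0.0655 or 0.0561 for mature neutrophil genes and 0.0736 or 0.0666 for the TIP60 complex, which had 0.0583 without MATIP EtOH replicate 1. The immediate-early list had 0.0910 without MATIP 4-OHT replicate 1 and 0.130 without replicate 2.

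The other 12 lists did not pass for the difference. Progenitor genes had a higher response in 9 and a lower one in 4 of 20, dendritic genes in 7 and 2 of 14, interferon genes in 13 and 4 of 27, p53 targets in 13 and 9 of 33, sterol genes in 11 and 10 of 26, cofactors in 7 and 3 of 16, and integrated stress genes in 6 and 16 of 24. Changed members were 3 of 13 in the mast and basophil list, 2 of 10 in the eosinophil, 5 of 10 in the erythroid, 4 of 5 in the lymphoid and 3 of 10 in the stromal list. Responses differed for 8491 genes, 3883 higher and 4608 lower in MATIP cells, against 4212 and 4213 with median-ratio and 4491 and 3899 with upper-quartile factors. The median difference of the TIP60 complex went from −0.63 to −0.38 (95% interval −0.86 to 0.42) with the length and GC trend removed. Adjusted over the list alone, 26 macrophage genes differed against 24 over all genes, 20 against 19 mature neutrophil genes, 3 against 5 erythroid genes, 23 against 22 p53 targets, 29 against 27 ribosome biogenesis genes and 19 against 16 TIP60 complex genes, with equal counts in the other 15 lists.

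**Figure D4:**
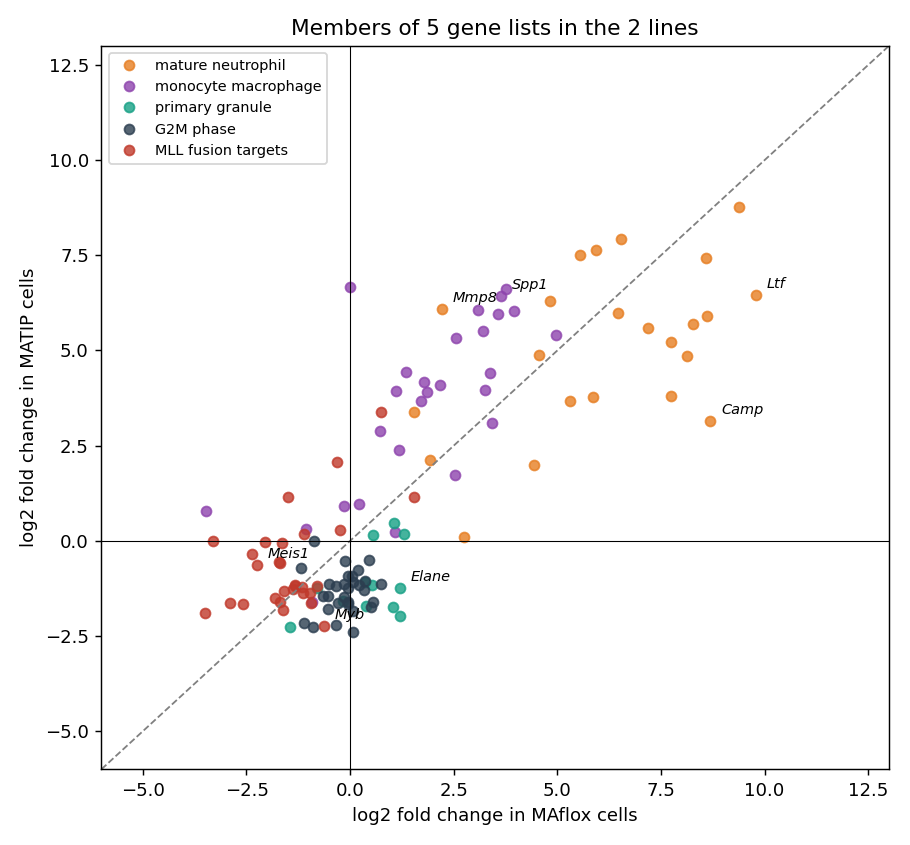
Log2 fold change with 4-OHT in MAflox (horizontal axis) and MATIP cells (vertical axis) of the members of 5 gene lists (1 point per gene, dashed line: equal change). Members of a list with 0 counts in both groups of a line are drawn at 0 for that line, and Camp lies at 8.70 and 3.13, Mmp8 at 2.21 and 6.09.

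Changes shared by the 2 lines were counted over all 13722 genes, with separate control libraries for each line. Genes that rose in both numbered 2780, against 1705 for independent lists (odds ratio 4.53), and genes that fell in both 2915, against 1698 (odds ratio 5.72). Opposite changes were fewer than for independent lists. Those up in MAflox and down in MATIP cells numbered 949 against 1756 (two-sided Fisher exact p = 1.09e-208). Those the other way numbered 708 against 1649 (two-sided Fisher exact p = 1.55e-299). Both p-values count genes as independent, which they are not, and do not measure the spread between samples. Of 7352 genes changed in both lines, 77.5% moved in the same direction and 62.1% moved further in MATIP cells. Across genes, which are not independent replicates, the log2 changes had a Pearson r of 0.57 and a Spearman rho of 0.50.

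The last comparison set the EtOH libraries of the lines side by side, since each response starts from its own baseline. Xist, the RNA of the inactive X chromosome, stood at 386 ± 31.2 CPM in MATIP against 0.174 ± 0.139 in MAflox cells. Genes of the Y chromosome were lower in MATIP cells, Uty by at least 1327-fold (0 counts), Kdm5d with a ratio of 534 to 15939 (2 counts), and Eif2s3y and Ddx3y with log2 differences of −10.99 ± 0.18 and −9.59 ± 0.15. Mecom was at least 548-fold lower in MATIP cells. Higher in MATIP were Zfp783 (4.77 ± 0.24), Mlph (4.72 ± 0.21), C1qtnf6 (4.42 ± 0.19) and Col6a3 (4.34 ± 0.13). Differences reached 4129 of 12784 autosomal genes, 127 of 407 on X and 4 of 4 on Y. The labels do not say how many founders each line had, and the sex-linked genes differed along with the genotype, so the genotype and the founder cannot be told apart.

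Sterol synthesis genes were higher in MATIP EtOH cells in 24 of 26 (median log2 0.75; camera adjusted p = 9.79e-27, adjusted p = 0.131 with an estimated correlation). Mature neutrophil genes were higher in 19 of 23 and lower in 3 (median 1.62; camera adjusted p = 3.9e-25, adjusted p = 0.131 with an estimated correlation), macrophage genes in 16 of 27 and lower in 4 (0.00162, adjusted p = 0.248 with an estimated correlation) and primary granule genes in 8 of 12 and lower in 4 (0.00629, adjusted p = 0.382 with an estimated correlation). Progenitor genes were lower in 10 of 20 and higher in 7 (camera adjusted p = 0.00162, adjusted p = 0.131 with an estimated correlation) and mast and basophil genes in 4 of 13 (0.0373, adjusted p = 0.226 with an estimated correlation). The last 3 of these calls were not kept in each refit: without MATIP 4-OHT replicate 1 or 2 the camera adjusted p was 0.106 or 0.102 for progenitor, 0.0766 or 0.0732 for primary granule and 0.0749 or 0.0731 for mast and basophil genes, and the last also missed 0.05 without either MAflox 4-OHT (0.0527, 0.0526) or MATIP EtOH library (0.0529, 0.0516), and with upper-quartile factors (0.0813). The other 15 lists did not pass. Changed members adjusted over the list alone were 18 against 17 over all genes for progenitor genes, 4 against 3 for erythroid genes, 18 against 16 for p53 targets, 3 against 4 for ribosome biogenesis and 14 against 12 for interferon genes, and equal for the other 16 lists. In all 4388 genes differed, 2780 higher and 1608 lower in MATIP cells, a share of 63.4% higher that was 57.9% with median-ratio and 44.9% with upper-quartile factors.

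The authors' deposited table gives a log2 fold change and an adjusted p for each line. Per the authors' deposited values, 8178 genes passed 0.05 in MAflox cells (4131 up, 4047 down) and 9749 in MATIP cells (5043 up, 4706 down). Of these, 8139 and 9572 were also called in the edgeR quasi-likelihood fit, all in the same direction as in the authors' deposited table. The authors' deposited table gives Kat5 a log2 change of 0.50 in MAflox and −2.28 in MATIP cells, Kmt2a −1.05 and 0.44, Hoxa9 −1.14 and −1.33, Meis1 −2.22 and −0.59, and Mllt10 −0.34 and −0.86.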

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

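All tests of explanations in this part, the robust fit of the length trend and the leaving out of Mecom were chosen after the results were seen, while the test of the difference between the responses was planned. Of 99 genes named for a treatment comparison, 86 had a different log2 response in the 2 lines (edgeR quasi-likelihood, Benjamini-Hochberg), 39 higher and 47 lower in MATIP cells, beside 61.9% of all genes. Most of the 99 were picked from these data for large or low-p changes within a line. That choice by itself raises the share that differs, so the excess over all genes is no evidence about these genes. A further 6 were named only because their responses differed most. By camera with its preset correlation 9 of 21 gene lists also differed, and none of the 9 with an estimated correlation (adjusted p 0.0761 to 0.384). They are set out here because the 2 lines did not respond alike, and values are log2 responses in MATIP minus MAflox.

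Differences were 2.78 for Spp1 and 0.44 for Lyz2 in the macrophage list, 2.09 for Cd74, 3.32 for Itgax and 0.45 for Tcf4 in the dendritic list, 3.96 for Fn1 in the stromal list, 4.76 for Vwf in the erythroid list, 0.87 for Mitf in the mast cell list, and 1.86 for Ear2 and −2.20 for Siglecf in the eosinophil list. The mature neutrophil list had 3.88 for Mmp8, −5.56 for Camp, −3.34 for Ltf, −2.53 for S100a8 and −1.16 for Stfa2l1, and the primary granule list −2.45 for Elane, −1.41 for Ctsg, −0.82 for Mpo and −2.78 for Nkg7. Genes named as the largest changes had 2.84 for Lyz1, −5.30 for Fcnb, −4.97 for Ceacam10, −2.48 for Ifitm6, −2.07 for Stfa3, −1.51 for Stfa2 and −4.70 for Ankrd22. The fitted value for Cxcl3 was −3.92, which depends on the prior count because MAflox EtOH had 0 counts. That for Ankrd22 rests on 2 counts over the MAflox EtOH libraries, and that for Lyz1 on 6 over the MATIP EtOH libraries, so their sizes are uncertain. Genes of MLL-fusion regulation and progenitors had 1.53 for Kmt2a, −0.56 for Mllt10, −0.23 for Hoxa9, 1.61 for Meis1, 1.27 for Mef2c, 1.61 for Flt3, 0.47 for Cd34, 2.23 for Cd93, −2.97 for Prom1, −1.60 for Myb, 0.88 for Dot1l, 0.56 for Kmt2b, −0.61 for Men1 and −0.36 for Psip1. The calls for Hoxa9, Cxcl3, Flt3, Cd34 and Ear2 did not hold under each alternative, with an adjusted p of 0.111 for Flt3 without MATIP 4-OHT replicate 1, 0.0949 for Cd34 without MATIP EtOH replicate 2, 0.244 for Ear2 without MAflox EtOH replicate 1, 0.122 for Cxcl3 with limma-voom and 0.134 for Hoxa9 with DESeq2. The Kmt2a difference was 0.79 with the trend on GC content and transcript length removed. The TIP60 complex had −2.82 for Kat5, 1.6 for Ep400, −2.01 for Ruvbl2 and −1.58 for H2afv.

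The median difference of all genes rose with transcript length, from −0.42 in the shortest of 5 equal groups to 0.47 in the longest. Of the single-gene values in this part, only that of Kmt2a is also given with the trend removed. Growth and division genes had −1.31 for Mcm2, −0.91 for Uhrf1, 0.54 for Dnmt1, 0.55 for Pole, 0.46 for Cenpe, −1.36 for Plk1, −2.46 for Ube2c, −1.87 for Cdc20, −1.67 for Pa2g4 and 1.41 for Utp20. The p53 targets had 0.63 for Trp53inp1 and 2.66 for Plk2. Metabolic and stress genes had −0.42 for Fdps, 1.30 for Hmgcs1, −0.75 for Shmt2, −1.93 for Phgdh, 0.89 for Slc7a5, 2.67 for Slc7a11, −0.42 for Hsph1, −3.09 for Bcat1 and −1.66 for Chdh. Interferon genes had 2.02 for Irf7 and −0.78 for Gbp3, lymphoid genes −1.22 for Cd79b and −2.22 for Lck, and the immediate-early gene list 1.82 for Klf6. Of the remaining named genes, the response was higher by 7.61 for Prl2c5, 7.32 for Klk1b11, 7.02 for Nr4a3, 6.43 for Fam181b, 6.40 for Gprc5b, 6.23 for Adgrl2, 4.01 for Armcx4, 2.08 for Col19a1, 1.86 for Adgrl4 and 1.72 for Cgnl1. The Prl2c5 and Gprc5b values rest on few counts in ethanol, so their sizes are uncertain. Lower responses were −5.25 for Smim6, −5.22 for Fbxo17, −3.34 for Rpph1, −3.10 for Snhg4, −2.26 for Ccdc116, −2.06 for Muc13, −2.05 for Cldn11 and −1.29 for Bhlha15, whose call was lost without MATIP 4-OHT replicate 2 (adjusted p = 0.0559). The median differences of the lists were 0.53 for MLL targets, 2.07 for macrophage, −1.42 for primary granule, −1.59 for mature neutrophil (95% interval −2.57 to 0.34), −0.88 for S phase, −1.21 for mitosis, −0.89 for ribosome biogenesis, −0.63 for the TIP60 complex (−0.38 with the GC and length trend removed, 95% interval −0.86 to 0.42) and 1.61 for immediate-early genes (95% interval −0.34 to 2.21).

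The first pattern weighed was the fall of MLL fusion targets in both lines. With the trend on GC content and transcript length removed, the list's median log2 change was −1.52 in MAflox (95% interval −1.84 to −1.10) and −1.10 in MATIP cells (−1.36 to −0.29). The fall was thus larger than that trend, which argues against length and GC content as the whole cause. With upper-quartile factors the median was −1.04 in MATIP cells (−1.22 to −0.19). Those factors moved the MATIP median of all genes only from 0.00 to 0.15, so they could not have brought the list to 0. Their result shows only that the fall exceeds the shift between these 2 scalings. Mecom, with 0 counts in both MATIP groups, was left out of the MATIP medians, and with it the last interval ends at 0. A direct effect of 4-OHT or Cre and the loss of a floxed allele cannot be told apart as the source, because 0 lines without a floxed allele were among the samples. Loss of Kat5 in MATIP cells and of the floxed allele in MAflox cells stay open, as untested sources.

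The second pattern was that ribosomal protein genes, a list written after the data were seen, rose in MAflox and fell in MATIP cells. With the robust trend removed the MAflox median went from 0.41 to 0.11 (95% interval 0.05 to 0.18). With an ordinary least-squares trend removed it was −0.23 (−0.31 to −0.15), or 0.02 (−0.07 to 0.10) when set against the median of all genes. The ordinary fit put all genes at −0.25, so −0.23 does not show a fall relative to other genes. The fits part on whether any rise remains, so a length-linked effect cannot be told apart from a rise in these genes in MAflox cells. In MATIP cells the fall stayed at −0.85 with the robust trend removed (−0.93 to −0.78) and at −0.88 with upper-quartile factors (−0.96 to −0.79). With the ordinary trend removed it was −1.50 (−1.55 to −1.35), or −1.09 (−1.14 to −0.94) when set against the median of all genes. The values with a trend removed argue against those trends as its whole cause. Upper-quartile factors moved the MATIP median of all genes only from 0.00 to 0.15, so their result shows only that the fall exceeds that shift. Members of this list move together (estimated correlation 0.77 in MATIP cells), so these intervals are too narrow. Loss of Kat5 stays open, untested, as a source of the MATIP fall.

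The third pattern was the different response of granule and macrophage genes. Between the treated libraries, the mature neutrophil list differed by a median of −0.18 (MATIP minus MAflox, 95% interval −0.67 to 1.14), while in ethanol it was higher in MATIP by 1.62, and 9 of 23 members were higher and 12 lower between the treated libraries, Mmp8 by 4.07 ± 0.06 and Camp by −3.32 ± 0.07, which leaves the starting level open for this list. Primary granule genes differed between treated libraries by −1.20 (−1.73 to −0.27) and macrophage genes by 2.36 (1.03 to 3.10), which argues against a starting level as their whole cause. With the length and GC trend removed the primary granule difference between the responses was −0.91 (−1.94 to −0.24). The genotype and the founder of each line stay open, as untested sources.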

How the results depend on the processing

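The tests for changes above 1.5-fold, the scalings of the lists and the removed trends were chosen after the data were seen, and the other alternatives were planned. No called change of a named gene or fixed list turned direction, but which direction held more genes turned in 10 of 17 alternatives in MATIP cells (upper-quartile 56.4% and median-ratio factors 52.8% up against 49.3%, DESeq2, no count filter, only the compared libraries, the 1.5-fold test and 4 fits leaving out a library), and with upper-quartile factors in the difference (53.5% higher against 45.7%) and the baseline (44.9% against 63.4%). The median of the added ribosomal protein list in MAflox cells turned from 0.41 to −0.23 with the ordinary trend removed. That fit put all genes at −0.25, and set against them the list stood at 0.02, so the turn is no fall relative to other genes. The median of oxidative phosphorylation in MAflox cells turned from 0.15 to −0.13 with the robust trend removed, and the cause was not tested. Over the alternatives, named genes kept direction and call in 3645 values, lost the call in 23 and gained it in 1, and counts stayed within 1.5 times in 249 values and moved in 13. List tests kept their call in 953 values, lost it in 66 and gained it in 52, of which the estimated correlation lost most. Gains included fry results, such as mast and basophil genes in MAflox cells (fry adjusted p = 4.27e-05, camera adjusted p = 0.247). Another was the lymphoid list for the difference (fry adjusted p = 0.000338, camera adjusted p = 0.0723). Fry does not compare a list with other genes, so these gains answer another question. List medians stayed in 384 values and moved in 36. With glmTreat, which by construction asks for a change above 1.5-fold, 3912 genes changed in MAflox (2170 up, 1742 down), 6283 in MATIP (3409 up, 2874 down), 4320 differed in response (2157 higher, 2163 lower) and 924 at baseline (566 higher, 358 lower). With upper-quartile factors 2527 genes were lower at baseline against 1608. Those factors also moved the baseline median of all genes from 0.02 to −0.05. When each library was left out in turn, the lone library of its group being assumed to vary like the others, 8123 to 9106 genes changed in MAflox, 9583 to 10608 in MATIP, 7760 to 8241 in response and 3173 to 4287 at baseline. In all 8 of these fits 7141 of 8947, 8695 of 10441, 6814 of 8491 and 2386 of 4388 genes kept call and direction.

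Calls of the difference were also lost without 1 library for Flt3 (without MATIP 4-OHT replicate 1, adjusted p = 0.111), Bhlha15 (without MATIP 4-OHT replicate 2, 0.0559), Cd34 (without MATIP EtOH replicate 2, 0.0949), Ear2 (without MAflox EtOH replicate 1, 0.244, or MATIP EtOH replicate 2, 0.0559) and Cxcl3 (without MAflox EtOH replicate 1, 0.0788, replicate 2, 0.111, or MATIP EtOH replicate 2, 0.0544; edgeR quasi-likelihood, Benjamini-Hochberg). Cxcl3 also missed the threshold with DESeq2 (0.0523) and limma-voom (0.122), and Ear2 with limma-voom (0.0569). Over the ethanol groups Ear2 had 11 and 19 counts and Cxcl3 0 and 26, and the cause of these losses was not tested.

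Same-numbered libraries did not deviate together (correlation of deviations −0.002 in MAflox and −0.039 in MATIP cells), so no pairing by number was seen in the counts. With 2 libraries per group this cannot show that the samples were unpaired. With the replicate number as a block, 8647 genes changed in MAflox (4352 up, 4295 down), 10153 in MATIP (4947 up, 5206 down) and 8155 differed in response (3690 higher, 4465 lower), with overlaps of 2631 up and 2846 down in both. Under the block, list calls were lost for erythroid genes in MATIP cells (camera adjusted p = 0.0567) and for mature neutrophil (0.0777), TIP60 complex (0.0826) and immediate-early genes (0.132) in the difference.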

Other observations

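The 5 gene lists of this part were written after the data were seen, and so were their tests. Lysosomal genes rose in both lines, in 38 of 49 members in MAflox (median log2 0.80) and 45 of 49 in MATIP cells (0.92). Ctsk, cathepsin K of osteoclasts, went from 0.700 ± 0.302 to 268 ± 17.8 CPM in MATIP cells (log2 8.63 ± 0.13, n = 2 libraries per group), and Psap, prosaposin, from 611 ± 13.5 to 15020 ± 188 CPM (4.62 ± 0.07). In MAflox cells their log2 changes were 3.0 ± 0.21 and 1.25 ± 0.06. Atp6v0d2, a proton pump subunit of osteoclasts and macrophages, rose by 4.17 ± 0.11 in MAflox and 6.29 ± 0.09 in MATIP cells. These genes were picked after their values were seen. Camera gave the lysosome list adjusted p of 3.8e-09 in MAflox (adjusted p = 0.0768 with an estimated correlation) and 3.81e-17 in MATIP cells (adjusted p = 0.0393 with an estimated correlation).

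Chemokine genes rose in 14 of 17 in MAflox (camera adjusted p = 3.09e-10, adjusted p = 0.0385 with an estimated correlation) and in all 17 in MATIP cells (2.58e-16, adjusted p = 0.0228 with an estimated correlation). Ccl6 reached 1900 ± 13.2 CPM in MAflox and 7904 ± 305 in MATIP cells, and Ccl24, which recruits eosinophils, fell in MAflox (−0.73 ± 0.30) and rose in MATIP cells (4.86 ± 0.25). All 6 subunit genes of the phagocyte NADPH oxidase rose in each line, Cybb by 5.41 ± 0.11 in MAflox and 5.12 ± 0.11 in MATIP cells (camera adjusted p = 8.01e-12 in MAflox, adjusted p = 0.00962 with an estimated correlation, and 0.00173 in MATIP, adjusted p = 0.0535 with an estimated correlation). Ribosomal protein genes rose in 68 of 79 in MAflox, with a median log2 change of 0.41 (camera adjusted p = 5.05e-05, adjusted p = 0.654 with an estimated correlation). With the robust trend on transcript length and GC content removed that median was 0.11. With the ordinary trend removed it was −0.23, or 0.02 when set against the median of all genes, which that fit put at −0.25. Ribosomal protein genes fell in 78 of 79 in MATIP cells (camera adjusted p = 2.07e-16, adjusted p = 0.284 with an estimated correlation). Oxidative phosphorylation genes rose in 17 of 33 and fell in 7 in MAflox (median log2 0.15, or −0.13 with the trend removed; camera adjusted p = 0.469), and rose in 6 and fell in 22 in MATIP cells (0.0245, adjusted p = 0.603 with an estimated correlation). Their median difference of −0.59 between the responses became −0.04 with the trend on transcript length and GC content removed.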
